A study of Arabidopsis thaliana with 12 samples.

How the data were processed

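Total RNA from the aerial parts of 4-day-old Arabidopsis seedlings was hybridised to Affymetrix-type oligonucleotide arrays with 22810 probe sets. The protocol text also describes the isolation of polysome-bound RNA, while each sample is labelled as total RNA, and the label was followed. The deposited values are linear probe set intensity, made by the authors with MAS5 per the labels, which state no software version, settings or detection calls. Checked on the values, each array had been scaled so that its mean without the lowest and highest 2% was about 500 (500 to 500.1). Signals ran from 0.1 to 51801.3, and none was 0 or below. Arrays carry no count of molecules, so their number, 3 per group, sets the precision.

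Groups were taken from the sample titles, which give genotype (Ler or atbzip16), light condition and replicate number, and which match the source names and treatments. The free-text descriptions of 6 samples name the other light condition, and were not used. The titles call the replicates biological, and the labels name no experiment day or array batch.

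Unless said otherwise, the choices described here were made before the data were examined. Signals were taken to log2 without a pseudocount. The 64 control probe sets were left out, and so were the 30% of the other 22746 with the lowest mean signal (under 41.6), which left 15922. A linear model with a mean per group was fitted over the 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a variance trend). The 5 contrasts were the light response in each genotype, the genotype difference in each light condition, and the interaction of both. P values were adjusted by the Benjamini-Hochberg method within a contrast, and a probe set was called at an adjusted p under 0.05. Errors given as ± are standard errors from that model, or from the model with the replicate block for the genes listed as called with it in the dark and in red light. Mean signals of a group are geometric means.

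Residuals of arrays with the same replicate number in different groups were positively correlated (18 pairs, 0.164 to 0.505). Most of this lay in replicate 1 (0.317 to 0.505 with itself). Replicates 2 and 3 correlated with their own number (0.164 to 0.292, median 0.181) little more than with each other (0.105 to 0.248, median 0.164), so the pairing of those 2 by number is weak. Values with replicate number as a fixed block are therefore printed beside a result where they change a call or move a count by over 1.5 times. The block leaves every log2 fold change as it is and alters only the error and the p.

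Probe sets were matched to genes through the platform's annotation, with names updated by Entrez ID from a gene table of assembly TAIR10.1, which also gave the order of genes along chromosomes. The annotation available held 14016 of the 22746 probe sets, 13513 of them with 1 gene and 503 with several, and lacked 8730. Of the 13513, 13436 were found in the gene table. It named no probe set for bZIP16 or any of the other G-group bZIP genes, PIF1, RGL2 or LHCB2.4, so these genes, planned to be reported, were not analysed here. Of 504 genes on 23 lists fixed in advance, 79 had a named probe set and 69 were tested. A gene with several probe sets was represented by the one with the highest mean signal. The 8 lists with 4 or more tested members were the light-harvesting and photosystem, chlorophyll synthesis, plastid-encoded, auxin, gibberellin, abscisic-acid-induced, cell wall expansion and seed-maturation genes. They were tested with limma's camera (preset correlation 0.01), with camera at an estimated correlation and with fry, adjusted over the 8 lists within a contrast. Tested members were 8 of 45 listed photosystem, 9 of 29 chlorophyll, 4 of 41 auxin and 5 of 30 gibberellin genes. They were 4 of 15 abscisic-acid-induced, 11 of 38 cell wall and 6 of 20 seed-maturation genes. A list result, called or not, covers only these members. The 12 lists with 1 to 3 tested members are given as values: light signalling, photorespiration, Calvin cycle, flavonoid, brassinosteroid, ethylene, circadian, cell cycle, root markers, breakdown of seed oil, heat shock, and wounding and defence. The 3 lists with no tested member were the G-group bZIP, abscisic acid metabolism and signalling, and mitochondrion-encoded genes.

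Named genes were chosen by a rule fixed in advance. It took, for each contrast, the 10 with the largest rise and the 10 with the largest fall among called probe sets with 1 gene, or all called ones and the 10 smallest p values where fewer passed. It also took up to 4 called members of each list, or the 2 with the smallest p. The same rule applied to the model with the replicate block, for the genotype differences and the interaction, was added after the data were seen.

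Correlations of log2 fold changes across probe sets compare the light responses, or the genotype differences, from contrasts that share no arrays, and the averaged genotype and light effects, which come from the same 12 arrays. Their errors come from leaving out each array in turn. Alternatives fixed in advance were quantile normalization, median centring, a pseudocount of 16, no low-signal filter, a filter at 50%, no variance trend, array weights, only the 6 arrays compared, the replicate block, only probe sets specific to 1 gene, a 2-fold minimum, a plain test per probe set without a shared variance, and leaving out each array. After the data were seen, 5 more were added: replicates 2 and 3 only, replicate 1 as a batch term, and the replicate block with the pseudocount, with the 50% filter or with quantile normalization. The alternatives foreseen for the level of bZIP16 were not run.

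The pipeline was tested on simulated data with 15922 probe sets, 50 of them changed at each fold, with shared differences between replicates. For the light response in the wild type, it recovered 30% of 2-fold changes without the block and 66% with it, and 80% and 90% of 4-fold changes. For the interaction it recovered 12% and 36% of 2-fold changes, and for the genotype difference in the dark 20% and 38%. The shared differences were drawn from the model with the block, which favours the block. Without them, the wild-type light response gave 46% without the block and 48% with it for 2-fold changes, and 90% and 84% for 4-fold changes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.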

Results

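Messenger RNA was measured with oligonucleotide arrays in the aerial parts of 4-day-old Arabidopsis thaliana seedlings. The seedlings had grown in the dark (etiolated) or under red light and long days at 0.5 µmol m-2 s-1. Each light condition held the wild type, Landsberg erecta (Ler), and atbzip16, a mutant line in the same background named after the transcription factor bZIP16. The 4 combinations had 3 biological replicates each, 12 arrays in all, and this number limits the precision of every value given here. Median signal per array lay between 148.3 and 186.1 and the highest signal between 34477 and 51801.3. After the removal of probe sets with low signal, 15922 were tested with limma, of which 8717 matched 1 named gene. No probe set carried the name of bZIP16, so the level of the targeted gene was not analysed here. The first principal component held 46.3% of the variance.

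**Figure D1:**
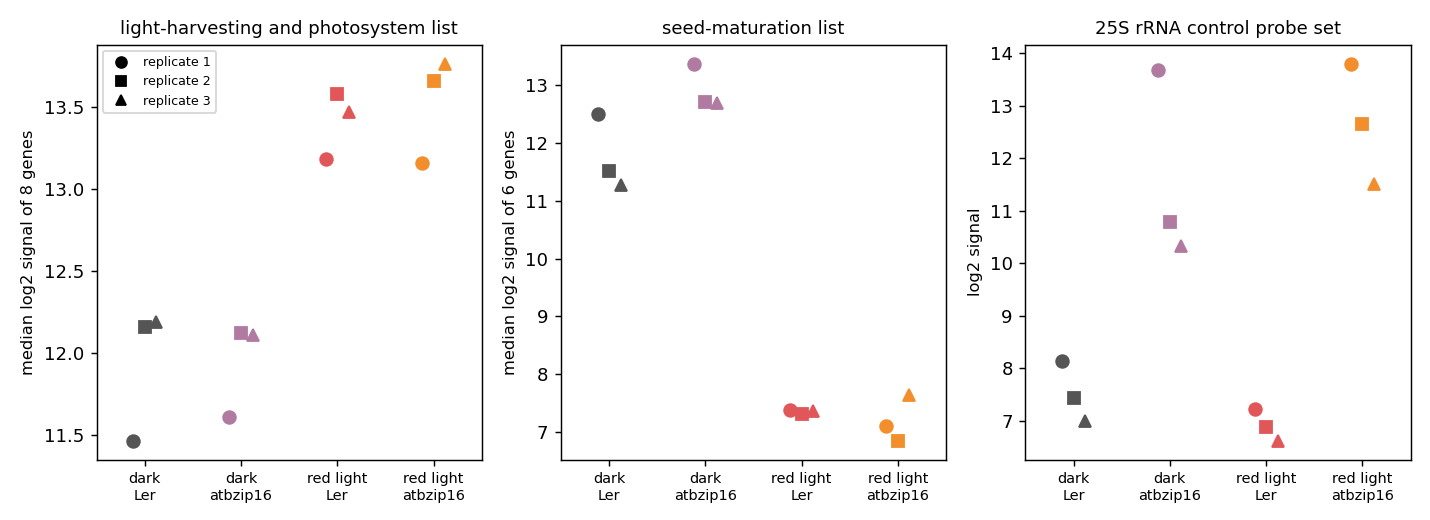
Each point is 1 array, with its group on the horizontal axis and replicate 1, 2 or 3 as circle, square or triangle. The vertical axes give the median log2 signal of 8 photosystem genes, the median log2 signal of 6 seed-maturation genes and the log2 signal of the 25S ribosomal RNA control probe set. The photosystem medians of the red-light arrays lie between 13.16 and 13.76, all above the dark arrays, and the 25S signal is higher in every atbzip16 array than in any Ler array.

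The first comparison asks how wild-type seedlings grown in red light differed from those grown in the dark. Transcripts made late in seed development were among those that fell most, and 6 of 8 measured light-harvesting and photosystem genes rose while 1 fell. Whether the dark and red-light samples of either genotype held different shares of ungerminated seeds was not tested. The falls of seed transcripts need not be light regulation within seedlings. PAP85, a vicilin-like seed storage protein, fell by 6.06 on the log2 scale (SE 0.25, n = 3 arrays per group, limma adjusted p = 5.22e-08), from a mean signal of 13734 to 205.8. M17, a late embryogenesis abundant protein, had a log2 fold change of -8.65 ± 1.05, and AT1G14950 one of -7.05 ± 0.33. AGL67, a MADS-box transcription factor, had a log2 fold change of -6.69 ± 0.99 and AT5G45690 one of -7.84 ± 0.90. LHCB4.2, a light-harvesting antenna protein of photosystem II, rose by 2.96 ± 0.26 (adjusted p = 1.2e-05). The largest rises among named genes were in AT4G28780, a GDSL-type esterase (5.16 ± 0.83), AT5G48490 (4.61 ± 0.85) and AT4G19530 (4.61 ± 0.63). Several of these genes lay near the low-signal limit in 1 condition, where a pseudocount of 16 brought M17 to -7.36, AGL67 to -4.97 and AT4G28780 to 3.82. All 39 named genes called in this comparison moved the same way in 3 of 3 replicate pairs. Such agreement is nearly given for genes called on these same arrays, here and in the later comparisons, and is no separate support.

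Among the lists fixed in advance, 6 of the 8 measured light-harvesting and photosystem genes rose in the wild type, 1 fell and 1 did not pass. Adjusted over the list alone 7 rose and 1 fell, as they did over all probe sets with replicate as a block (PSBW 1.12, adjusted p = 0.000111). PSAE-1 rose by 2.03 ± 0.47 and PSAN by 1.65 ± 0.21, both subunits of photosystem I, and the list median was 1.45 (camera adjusted p = 1.76e-07, adjusted p = 0.105 with an estimated correlation, and 0.0104 with both that and the block). The member that fell, LHCB4.3 (mean signal 420.3 in the dark and 210.0 in red light), a further antenna protein, was singled out after its values were seen. All 6 measured seed-maturation genes fell, over all probe sets and adjusted over the list alone, with a median of -5.14 (camera adjusted p = 6.83e-11, and 0.00171 with an estimated correlation). They included the oleosin OLEO3 (-3.71), the oleosin-family gene AT3G01570 (-5.24), the cupin AT2G28490 (-5.04) and the late embryogenesis abundant protein AT3G15670 (-2.64). Of 4 auxin genes, 3 fell and 1 did not pass, and all 4 fell adjusted over the list alone or with replicate as a block (IAA29 -0.61, adjusted p = 0.0317). HAT2 (-0.68 ± 0.17) and WES1, a GH3 enzyme that conjugates auxin (-0.50 ± 0.12), fell, and neither passed after median centring. The auxin list had a median of -0.65 (camera adjusted p = 0.00281, and adjusted p = 0.0886 with an estimated correlation).

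Of 11 expansin and xyloglucan endotransglucosylase genes, which act on the cell wall during growth, 1 rose and 4 fell in the wild type, with the same counts adjusted over the list alone, and EXPB1 fell too with replicate as a block (-0.91, adjusted p = 0.0356). EXPA9 (-2.89 ± 0.19) and XTH33 (-2.31 ± 0.30) fell, while EXPA16 rose by 2.47 ± 0.20. The list as a whole was not called by camera (median -0.04, camera adjusted p = 0.156), but it was by fry (fry adjusted p = 0.00996). CHLM, a methyltransferase of chlorophyll synthesis, was the only 1 of 9 chlorophyll genes to rise (from a mean signal of 3326 to 7137, limma adjusted p = 0.00125, also adjusted over the list alone), and the list median was 0.05 (camera adjusted p = 0.517). With replicate as a block, 3 chlorophyll genes rose and 3 fell. Of 67 plastid-encoded genes, 12 rose and 3 fell, 17 and 5 adjusted over the list alone, and 32 and 8 with replicate as a block. The plastid genes included psbA (1.15 ± 0.23) and ndhK (1.06 ± 0.20), and had a median of 0.31 (camera adjusted p = 2.91e-05). That list was no longer called with an estimated correlation (adjusted p = 0.254), by fry (fry adjusted p = 0.0867) or after quantile normalization, with or without the block. None of 5 gibberellin genes (median 0.13, camera adjusted p = 0.448) or of 4 genes induced by abscisic acid (median 0.40, camera adjusted p = 0.183) passed, over all probe sets or adjusted over the list alone, and with replicate as a block 1, COR47, did (0.37, adjusted p = 0.0215). In lists with fewer than 4 measured members, HPR, the hydroxypyruvate reductase of photorespiration, rose by 1.80 ± 0.14 and the brassinosteroid transcription factor BIM1 fell by 0.89 ± 0.13.

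In the wild type, limma called 1820 probe sets, 899 higher and 921 lower in red light, of which 376 and 485 changed at least 2-fold. With replicate as a block it called 3761, 1758 higher and 2003 lower, including all 1820. Of the calls, 49.4% were higher, and 67.4% were after median centring, which moved the median log2 fold change of all probe sets from -0.06 to 0.08. Counts of higher against lower probe sets are therefore relative to the scaling. Without dark Ler replicate 2 the count was 1079 and without dark Ler replicate 3 it was 1056. Among the genes named here, the calls of WES1 and HAT2 (without dark Ler replicate 3 or red-light Ler replicate 2) and of PSAE-1 (without red-light Ler replicate 2 or 3) ended when 1 array was left out, with log2 fold changes between -0.56 and -0.44, between -0.76 and -0.62, and between 1.60 and 2.38 over all such fits.

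The second comparison asks the same question of atbzip16. M10, a late embryogenesis abundant protein, fell by 8.46 ± 0.62 on the log2 scale (limma adjusted p = 2.39e-06, n = 3 arrays per group), and AGL67 had a log2 fold change of -8.22 ± 0.99. AT1G14930 fell by 8.09 ± 1.07, and PAP85 had a log2 fold change of -6.87 ± 0.25, from a mean signal of 29204 to 250.3. The largest rises among named genes were in AT4G28780 (4.68 ± 0.83), AT5G48490 (4.62 ± 0.85) and AT2G34620 (3.82 ± 0.87), and LHCB4.2 rose by 2.98 ± 0.26. With a pseudocount of 16, M10 had a log2 fold change of -7.19, AGL67 one of -6.33, AT1G14930 one of -6.45 and AT4G28780 one of 3.54. All 46 named genes called here moved the same way in 3 of 3 replicate pairs.

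In atbzip16, 7 of 8 light-harvesting and photosystem genes rose and 1 did not pass, and adjusted over the list alone 7 rose and 1 fell. The list median was 1.41 (camera adjusted p = 3.79e-07, adjusted p = 0.117 with an estimated correlation, and 0.0122 with both that and the block), with PSAN at 1.71 ± 0.21 and PSBY at 1.49 ± 0.15. All 6 seed-maturation genes fell, with the same count adjusted over the list alone and a median of -6.18 (camera adjusted p = 1.41e-11, and 0.00138 with an estimated correlation). Of 4 auxin genes 2 fell, 3 adjusted over the list alone, and with replicate as a block also HAT2 (-0.46, adjusted p = 0.0135). The auxin list had a median of -0.52 (camera adjusted p = 0.0141, and adjusted p = 0.117 with an estimated correlation). WES1 fell by 0.59 ± 0.12, a call that median centring ended. Of 11 cell wall genes 1 rose and 4 fell, with the same counts adjusted over the list alone. EXPA9 (-2.25 ± 0.19), XTH19 (-1.77 ± 0.36) and XTH33 (-1.59 ± 0.30) fell, while EXPA16 rose by 2.02 ± 0.20. The cell wall list had a median of -0.39 (camera adjusted p = 0.0349, and adjusted p = 0.141 with an estimated correlation), and it was not called without dark atbzip16 replicate 2 (median -0.44) or red-light atbzip16 replicate 2 (median -0.41).

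CHLM (1.24 ± 0.17) and AT1G74470, a geranylgeranyl reductase (0.80 ± 0.19), rose among 9 chlorophyll genes in atbzip16, with the same count adjusted over the list alone, and HEME1 (0.65, adjusted p = 0.000565) rose too with replicate as a block. The list median was 0.28 (camera adjusted p = 0.0776, and 0.0339 with replicate as a block, but 0.118 with the block and an estimated correlation). The call of AT1G74470 ended after quantile normalization and without dark atbzip16 replicate 1 or red-light atbzip16 replicate 2 or 3 (log2 fold changes between 0.67 and 0.99 over all fits without 1 array). Of 67 plastid-encoded genes 16 rose and 0 fell by limma, 24 and 2 adjusted over the list alone, 32 and 5 with replicate as a block. Their median was 0.35 (camera adjusted p = 3.38e-06, and adjusted p = 0.246 with an estimated correlation), and they included psbA (1.12 ± 0.23) and petD (1.16 ± 0.23). Of 5 gibberellin genes 1 rose and 1 fell, also adjusted over the list alone: the receptor GID1B fell by 1.11 ± 0.22 and the F-box protein SLY1 rose by 0.66 ± 0.17. The call of SLY1 ended without any 1 of replicates 2 and 3 of both atbzip16 groups (0.57 to 0.76 over all fits without 1 array), and the gibberellin list was not called (median -0.13, camera adjusted p = 0.856). None of 4 genes induced by abscisic acid passed, over all probe sets or adjusted over the list alone (median -0.10, camera adjusted p = 0.856).

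Some members of the small lists passed in atbzip16 and not in the wild type, and limma called the difference between genotypes for none of them over all probe sets. FHL, a partner of phytochrome A import, fell by 1.31 ± 0.21 in atbzip16, with -0.57 ± 0.21 in the wild type. STZ, a stress-induced zinc-finger protein, fell by 2.52 ± 0.42, with -0.62 ± 0.42 in the wild type, and the heat shock gene AT1G53540 fell by 2.91 ± 0.63, with -0.80 ± 0.63 in the wild type. Adjusted over the list alone, the difference between genotypes passed for 1 of 2 light signalling genes and 0 of 2 heat shock genes. It also passed for 1 of 1 wound genes, where a list of 1 leaves the p unadjusted. HPR rose by 1.77 ± 0.14 and BIM1 fell by 1.16 ± 0.13, as they did in the wild type.

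In atbzip16, limma called 2224 probe sets, 1129 higher and 1095 lower in red light, of which 434 and 590 changed at least 2-fold. With replicate as a block it called 4221, 2091 higher and 2130 lower, including all 2224. Of the calls, 50.8% were higher, and 65.9% were after median centring, which moved the median log2 fold change of all probe sets from -0.02 to 0.09. Without red-light atbzip16 replicate 2 the count was 1372 and without red-light atbzip16 replicate 3 it was 1414. Among the genes named for this comparison, AT2G34620 lost its call without the same arrays (log2 fold changes between 2.84 and 4.62 over all fits without 1 array).

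Both genotypes shared most of the light response. Of the probe sets called, 709 were higher and 599 lower in both, where independent lists of these sizes would share 63.7 and 63.3, and 0 were called in opposite directions by limma. Across probe sets, which are not independent replicates, the log2 fold changes of the genotypes had a Pearson correlation of 0.81 (jackknife SE 0.06) and a Spearman correlation of 0.69. The Pearson correlation was much lower without the low-signal filter, as given below with the dependence on processing. AT1G14950, AT5G45690, AGL67 and M17 fell in both genotypes, and AT4G28780, AT5G48490 and LHCB4.2 rose in both.

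**Figure D2:**
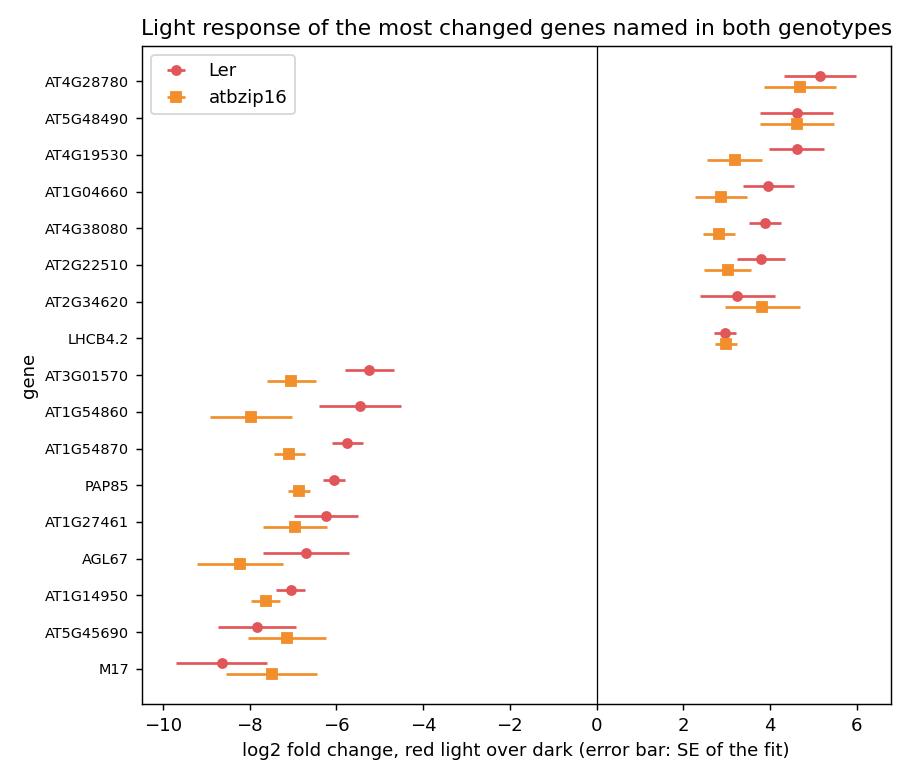
The horizontal axis gives the log2 fold change of red light over dark with its SE, for genes among the most changed that were named in both genotypes, and the vertical axis lists the genes. Circles are Ler and squares atbzip16. All lie on the same side of 0 in both genotypes, from M17 (-8.65 in Ler and -7.49 in atbzip16) to AT4G28780 (5.16 and 4.68). The genes were picked for large called changes, so this agreement is nearly given and is no separate support.

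The interaction asks whether the light response differed between genotypes. By limma, 0 probe sets were called (smallest adjusted p = 0.178), and 567 had an unadjusted p under 0.05 where 796 would by chance. Over the fits without 1 array the count was 0 to 2, with 2 without red-light Ler replicate 1 and 1 without red-light Ler replicate 3 or red-light atbzip16 replicate 1. The outer envelope protein gene ATOEP16-2 had the smallest adjusted p, with a difference of -3.34 ± 0.48, the light response of atbzip16 being the lower. With replicate as a block, limma called 54 probe sets, 4 higher and 50 lower, and among them were ATOEP16-2 (adjusted p = 0.00402), AT5G44310 (-2.51, adjusted p = 0.000501), AT3G57020 (-2.42, adjusted p = 0.000501), M10 (-3.59, adjusted p = 0.0157) and the tubulin gene TUB1 (0.90, adjusted p = 0.0216). Of the 8 tested lists, camera called 0 for the interaction, with 3 at an unadjusted p under 0.05. With the block it called the chlorophyll list (median 0.34, camera adjusted p = 0.00408, and adjusted p = 0.0896 with an estimated correlation). No member of a tested list passed in the interaction over all probe sets, with or without the block. Adjusted over the list alone, 1 seed-maturation gene was lower without the block, and 2 seed-maturation genes and 1 cell wall gene were with it.

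The third comparison asks how atbzip16 differed from the wild type in the dark. AT1G06700, annotated as a protein kinase gene, had the smallest adjusted p, and its signal was 73.8 in atbzip16 and 3287 in Ler, a log2 fold change of -5.48 ± 0.16 (limma adjusted p = 1.23e-09, n = 3 arrays per group). Also lower were probe set 254452_at (-5.73 ± 0.79), the helicase gene NIH (-1.19 ± 0.18), probe set 248863_at (-0.90 ± 0.11) and MYC3, a transcription factor of jasmonate responses (-0.88 ± 0.14). Higher in atbzip16 were AT1G35612 (2.52 ± 0.35), AT2G15010, a thionin-like gene (1.76 ± 0.25), and the asparaginase gene ASPGB1 (0.88 ± 0.14), together with probe sets 253904_at (3.80 ± 0.52) and 245161_at (2.00 ± 0.29). These 10 were all that limma called, 5 higher and 5 lower, each in the same direction in 3 of 3 replicate pairs.

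With replicate as a block, limma called 290 probe sets in the dark, 200 higher and 90 lower in atbzip16, including the 10. Among the largest rises were AT1G47540 (2.84 ± 0.60, block adjusted p = 0.026), the defensin PDF2.1 (2.67 ± 0.43, 0.00523), AT3G21380 (from a mean signal of 106.5 to 526.2, 0.00538) and the beta-glucosidase BGLU19 (2.21 ± 0.49, 0.0334). Among named genes, the largest falls after AT1G06700 were in its neighbour AT1G06690 (-4.80 ± 0.89, 0.0124), AT5G35940 (-1.58 ± 0.34, 0.0309) and AT4G01390 (-1.49 ± 0.29, 0.0158).

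Of 6 seed-maturation genes, 0 were called in the dark by limma, and 1 rose adjusted over the list alone. The block gave 1 rise over all probe sets and 4 adjusted over the list alone. The list had a median difference of 1.21, with 0.84, 1.26 and 1.52 in the 3 replicate pairs (camera adjusted p = 0.00124, and adjusted p = 0.0619 with an estimated correlation). AT2G28490 had a difference of 1.60, AT3G01570 of 1.33, PAP85 of 1.09 ± 0.25, which passed with the block (adjusted p = 0.0154), and OLEO3 of -0.36. The 67 plastid-encoded genes had a median of 0.10 with 0 called by limma (also 0 adjusted over the list alone) and a camera adjusted p of 0.0103, but 0.720 with an estimated correlation. By fry the list was not called (fry adjusted p = 0.646). The camera call also ended after quantile normalization and without dark Ler replicate 1 (median 0.03) or 3 (0.07), or dark atbzip16 replicate 2 (0.04) or 3 (0.05). The photosystem (median -0.02), auxin (-0.09), cell wall (-0.03), chlorophyll (-0.12), gibberellin (0.15) and abscisic-acid-induced (-0.37) lists were not called, and 0 of their members passed by limma, over all probe sets or adjusted over the list alone. The plastid gene psbN (0.77, adjusted p = 0.0199) rose and AT1G74470 of the chlorophyll list (-0.49, adjusted p = 0.0138) fell with replicate as a block.

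At an unadjusted p under 0.05 limma had 1003 probe sets for the genotype difference in the dark, where 796 would by chance. AT1G06700 was called in all fits that left out 1 array, with values between -5.50 and -5.44, and the other 9 calls each ended in some of them. The count was 1 without dark Ler replicate 2, dark Ler replicate 3, dark atbzip16 replicate 1 or dark atbzip16 replicate 3, 2 without dark atbzip16 replicate 2, 39 without dark Ler replicate 1 and 27 without red-light Ler replicate 1.

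The fourth comparison asks how atbzip16 differed from the wild type in red light. AT1G06700 was again lower, with a signal of 48.3 in atbzip16 and 4476 in Ler, a log2 fold change of -6.53 ± 0.16 (limma adjusted p = 1.36e-10, n = 3 arrays per group). Also lower were AT1G13930 (-1.06 ± 0.12) and probe sets 248863_at (-0.95 ± 0.11) and 256017_at (-0.99 ± 0.15). AT1G55170 (1.08 ± 0.15) and probe set 256166_at (4.57 ± 0.64) were higher. These 6 were all that limma called, 2 higher and 4 lower, each in the same direction in 3 of 3 replicate pairs. The next smallest p belonged to probe set 253114_at (-1.03 ± 0.16, adjusted p = 0.0518), which passed with replicate as a block (adjusted p = 0.00173) and not without it.

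With replicate as a block, limma called 87 probe sets in red light, 34 higher and 53 lower, including the 6. Among them AT1G42705 (3.48 ± 0.68, block adjusted p = 0.0365) and AT1G29680 (2.32 ± 0.43, 0.0283) rose. AT1G14930 (-2.91 ± 0.59, 0.0458), the adenine nucleotide carrier gene TAAC (-2.31 ± 0.42, 0.0272), AT2G37870 (-1.69 ± 0.24, 0.00724) and AT3G53980 (-1.50 ± 0.30, 0.0458) fell.

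Of 4 genes induced by abscisic acid, 0 were called in red light by limma, and 1 fell adjusted over the list alone. The block gave no fall over all probe sets and 3 adjusted over the list alone. The list had a median of -0.78, with -0.70, -0.92 and -0.80 in the 3 replicate pairs (camera adjusted p = 0.000169, and 0.0316 with an estimated correlation). The dehydrin LTI30 had a difference of -1.40 ± 0.33 and AT3G02480 one of -0.93, and neither passed over all probe sets. The plastid-encoded list had a median of 0.19 (camera adjusted p = 7.43e-06, but 0.398 with an estimated correlation and 0.584 by fry). Of its 67 genes 0 were called by limma, also adjusted over the list alone, and psbH (0.51, adjusted p = 0.0223) was with replicate as a block. The photosystem (median 0.05), auxin (0.04), cell wall (-0.12), chlorophyll (0.10), gibberellin (-0.01) and seed-maturation (0.12) lists were not called, and 0 of their members passed by limma, over all probe sets or adjusted over the list alone.

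At an unadjusted p under 0.05 limma had 817 probe sets for the genotype difference in red light, where 796 would by chance. AT1G06700 was called in all fits that left out 1 array (-6.65 to -6.34), and the other 5 calls each ended in some of them. The count was 1 without red-light atbzip16 replicate 2 or 3, 3 without dark Ler replicate 2 or dark atbzip16 replicate 1 or 3, and 25 without red-light Ler replicate 1.

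The genotype differences in both light conditions were weakly related over all probe sets, while 92.9% of the 14 probe sets called in either had the same sign in both. The log2 fold changes had a Pearson correlation of 0.18 (jackknife SE 0.14) and a Spearman correlation of 0.15, and AT1G06700 and probe set 248863_at were the 2 called lower in both. Averaged over light, limma called 35 probe sets between genotypes and 3940 between light conditions, 331 and 6124 with replicate as a block. The averaged genotype differences included AT1G06690 (-4.38), NIH (-1.02), MYC3 (-0.81) and the histone gene HTB2 (-0.62). Averaged genotype and light effects had a Pearson correlation of -0.17 (jackknife SE 0.14) and a Spearman correlation of -0.02 across probe sets.

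**Figure D3:**
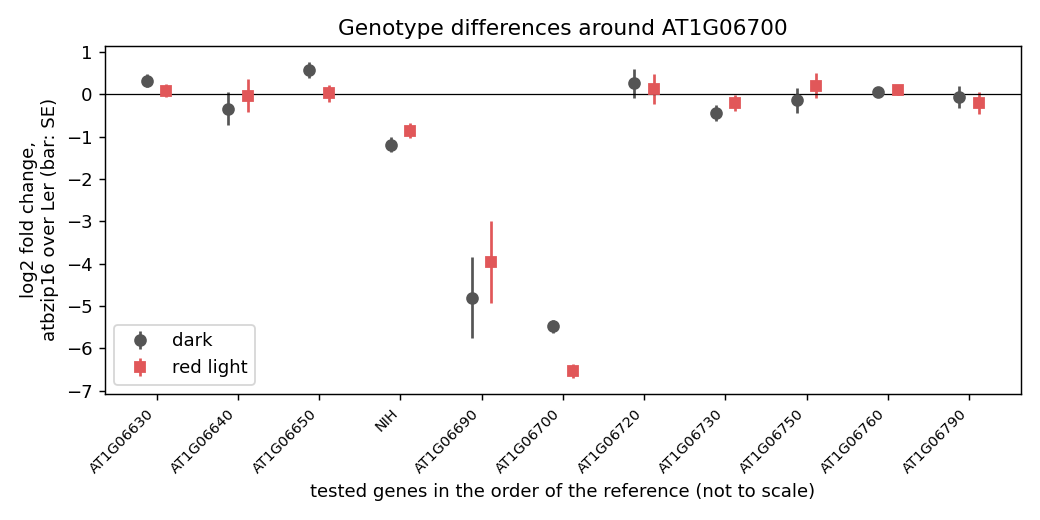
The vertical axis gives the log2 fold change of atbzip16 over Ler with its SE, and the horizontal axis lists AT1G06700 and the 5 tested genes on each side of it in reference order, not to scale. Circles are dark and squares red light. AT1G06690 lies at -4.80 in the dark and -3.96 in red light, NIH at -1.19 and -0.86, and the nearest gene on the other side, AT1G06720, lies at 0.26 and 0.13.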

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

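The tests of seed share, chromosome position, single arrays and other ribosomal RNA, and the naming of genes from the model with the replicate block, were chosen after the results were seen.

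The seed-maturation list was higher in dark-grown atbzip16 by camera (adjusted p = 0.00124), but not with an estimated correlation (adjusted p = 0.0619) or by fry (0.0576). Its median difference was 1.21 over 6 genes, none of which passed by limma over all probe sets without the replicate block and 1 adjusted over the list alone, and 0.12 in red light. A larger share of ungerminated seeds in those samples was predicted to raise all of them by similar amounts. The members moved apart by more than their replicate spread (permutation p = 0.00095 over 100000 permutations, and 0.0401 without OLEO3, which had -0.36). That test cannot decide the question, since seeds would raise each transcript according to its level in seeds relative to seedlings, which was not measured. A larger seed share therefore stays open. Over all tested probe sets, 122 were at least 8-fold lower in red light averaged over genotypes, members of the list such as PAP85 among them. They had a median genotype difference of 1.34 in the dark, with 111 above 0, and 0.26 in red light. A higher level in dark-grown atbzip16 itself helps a probe set reach that limit. Seeds at uneven stages stay open too. So does a slower decline of these transcripts in atbzip16, which was not tested and which seedlings of a single age cannot show. The brightest member, PAP85, had a signal of 29204 and may be compressed, which was not tested.

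The light response differed between genotypes at 54 probe sets by limma with the replicate block, 4 higher and 50 lower in atbzip16, and at 0 without it, where 567 had an unadjusted p under 0.05. The differences were -3.59 for M10, -3.43 for AT4G31830, -3.34 for ATOEP16-2, -2.87 for AT5G42290, -2.51 for AT5G44310 and -2.42 for AT3G57020. They were -2.33 for AT5G01300, -2.30 for 255048_at, -2.26 for AT5G07330, -2.25 for AT2G25890, -2.24 for 261077_at, -2.21 for AT3G17520, -1.84 for AT1G04560 and -1.81 for AT2G15010. AT4G32460 (0.90) and TUB1 (0.90) were among the 4 higher. The 122 probe sets at least 8-fold lower in red light had a median interaction of -1.11, with a median genotype difference of 1.34 in the dark and 0.26 in red light. The interaction is the genotype difference in red light minus that in the dark. Some called genes, singled out for opposite signs, were higher in atbzip16 in every dark pair and lower in every red-light pair. They were ATOEP16-2 (1.66 in the dark and -1.68 in red light), AT4G31830 (1.46 and -1.97) and AT5G42290 (1.47 and -1.39). AT3G57020 (1.61 and -0.81), AT5G07330 (0.95 and -1.31) and AT2G25890 (1.01 and -1.24) did the same. For these a higher level in the dark is only part of the interaction, and for the other called probe sets its part was not tested. AT1G14930 (-3.71, block adjusted p = 0.0967) and TAAC (-2.97, block adjusted p = 0.0559) were likewise higher in atbzip16 in every dark pair and lower in every red-light pair, but their interaction did not pass. The chlorophyll list had a median interaction of 0.34 with the block (camera adjusted p = 0.00408, and adjusted p = 0.0896 with an estimated correlation).

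AT1G06700 was lower in atbzip16 in both light conditions, and so were its neighbours AT1G06690 (averaged over light -4.38) and NIH (-1.02), while AT1G06720 on the other side had 0.26 and 0.13. A low spot on 1 array or in 1 group is argued against, since the difference nearest to 0 over all fits without 1 array was -5.44. A changed chromosome segment at this place in the mutant line stays open and has no support from a separate test. Of 8584 genes in chromosome order, 167 had a called difference averaged over light with replicate as a block, 2 of them among the 10 nearest to AT1G06700, and 1.71% of windows of this size (147) held as many, but the 2 are the neighbours that prompted the count. Outside the window of AT1G06700, genes called in this way lay next to each other in 7 pairs, where shuffled orders had a median of 3 (permutation p = 0.0351), among them MYC3 and AT5G46780, the plastid genes psbN and psbH, which lie on no nuclear chromosome, and AT5G19590 (-0.31) and AT5G19630 (0.81), which went opposite ways. A regulatory difference between the genotypes stays open, untested.

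The 25S ribosomal RNA control probe set, left out of the comparisons, was higher in atbzip16 by 4.07 ± 0.74 in the dark (limma adjusted p = 0.00736 over the controls) and by 5.74 ± 0.74 in red light (0.000233). Its signals were 98.5 to 282.8 in the 6 Ler arrays and 1285.2 to 14256.3 in the 6 atbzip16 arrays (exact permutation p = 0.005 within light conditions). More degraded RNA in atbzip16 is unlikely as the cause, since the 3' to 5' ratio of GAPDH differed by 0.0699 on the log2 scale (exact permutation p = 0.595) and that of actin by -0.0203. Over the arrays of both genotypes the log2 ratio was 0.425 to 1.16 for GAPDH and 3.20 to 4.07 for actin. The 3' signal was thus the higher on every array, and by much more for actin. More ribosomal RNA of every kind stays open: the 5S control differed by -0.455, but its signals lay near the low-signal limit (6.2 to 62.8), so it decides nothing. The only 1 of 64 controls called in each genotype comparison was this one, and no biological explanation was tested. Whatever raised it parted the genotypes in all arrays, so its effects cannot be told apart from the genotype differences given here.

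Other splits of the 6 arrays of each pairwise comparison were too few, at 10, for a share under 0.05. The real split had 1820 probe sets for the wild-type light response and the highest other 1, 2224 and 0 for atbzip16, 10 and 0 for the genotype difference in the dark, and 6 and 0 in red light, so that in each of them only 1 split, the real one, reached its count. With the block, the real splits had 3761, 4221, 290 and 87, and the highest others that part every pair 0, 0, 0 and 2, over 4 splits each. For the interaction without the block, the real count of 0 is reached by any split (100 of 100 drawn from 200, the highest with 35), so the splits decide nothing. With the block, 3 of 32 splits reached the real 54. The highest, at 331, exchanges the genotypes in all 3 red-light pairs and so measures the genotype difference common to both light conditions, and the other, at 101, exchanges them in pairs 2 and 3 in red light.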

How the results depend on the processing

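The replicate block combined with the pseudocount, the 50% filter or quantile normalization, replicates 2 and 3 only, and the batch term were chosen after the data were seen. Counts are given in the order light response in the wild type, light response in atbzip16, genotype difference in the dark, genotype difference in red light, and interaction, against 1820, 2224, 10, 6 and 0. Array weights gave 3877, 4395, 354, 103 and 40. The replicate block gave 3761, 4221, 290, 87 and 54. Replicates 2 and 3 only gave 4248, 4657, 641, 461 and 242, and replicate 1 as a batch term 3936, 4423, 336, 130 and 78. The block with a pseudocount of 16 gave 3881, 4352, 382, 98 and 97, with 50% left out 3517, 3884, 318, 93 and 66, and with quantile normalization 3618, 4246, 330, 79 and 68. Using only the 6 arrays compared gave 1096 for the wild type, 16 in the dark and 1 in red light. Specific probe sets with 1 gene gave 858, 1049, 7, 3 and 0, since fewer were counted, and a 2-fold minimum 861, 1024, 7, 4 and 0. A plain test per probe set, which has no shared variance and also uses only the 6 arrays compared, gave 249, 697, 1 and 0 (845 at an unadjusted p under 0.05) for the pairwise comparisons. For the genotype difference in the dark, quantile normalization gave 15, median centring 6, the pseudocount 29, no filter 18 and no variance trend 3, and in red light quantile normalization gave 9 and median centring 4. The pseudocount gave 1 for the interaction. Where no reason is given, the cause was not tested. No value could be had for the interaction from the 6 arrays compared or from the plain test.

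Leaving out 1 array gave 1056 to 2061, 1372 to 2504, 1 to 39, 1 to 25 and 0 to 2. With the block it gave 2561 to 4065, 3103 to 4518, 107 to 396, 17 to 202 and 16 to 94. The block count in the dark was lowest without dark atbzip16 replicate 3, that in red light lowest without red-light Ler replicate 3 and highest without red-light Ler replicate 1, and that of the interaction lowest without dark atbzip16 replicate 3 and highest without red-light Ler replicate 1. The correlation between light responses (0.81) was 0.48 without a filter, since probe sets near background enter, and 0.89 with 50% left out. It was 0.74 to 0.81 over the fits without 1 array, that between genotype differences 0.10 to 0.24, and that between genotype and light -0.23 to -0.08.

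Of the values of named genes under the alternatives, 6619 kept their sign and side of the threshold, 87 changed sign while called in neither fit, 507 passed only under the alternative, 207 no longer passed, and 1 changed sign and call: PYK10 of the root marker list, not called in the wild-type light response (0.05), had -0.32 with the block and quantile normalization. For the lists these were 1014, 56, 48, 24 and 0 by camera or fry. Of the named calls, 30 of 39 in the wild-type light response, 36 of 46 in atbzip16, 1 of 10 in the dark and 1 of 6 in red light held in every fit without 1 array. Signal over background limits the folds of genes near 41.6, which a pseudocount shrinks.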

Other observations

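The test of the sample descriptions was set before the result was seen, and the comparison of replicate 1 with the others, the seed share in red light, the 8-fold set and the families of genes were chosen after.

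The lists with few measured members hold some further biology. ICL, the isocitrate lyase that turns seed oil into sugar, had a signal of 22474 in dark-grown atbzip16 and 13570 in dark-grown Ler, a difference of 0.73 that passed with the replicate block and not without it (block adjusted p = 0.00697), while AIM1 had 0.05 and SDP1 0.29. Among Calvin cycle genes, SBPASE had -0.54 in the dark (block adjusted p = 0.0199), and RCA had 0.53 and 0.67 and PRK 0.37 and 0.76 for the light response in the wild type and in atbzip16, none called without the block. PYK10, on the fixed list of root markers, had a mean signal of 18227 to 19909 in the 4 groups, and no contrast called it. The labels name aerial parts, and this gene alone cannot show whether root tissue was present. EXPA18, on the same list, had 1.52 and 0.81 for the light responses and was not called. The heat shock gene ATHSP22.0 fell by 2.36 in atbzip16 in red light, with -1.34 in the wild type, which passed with the replicate block (adjusted p = 0.038), and in atbzip16 it lost its call without any 1 of the 3 dark atbzip16 arrays or red-light atbzip16 replicate 2 or 3 (-3.06 to -1.51 over all fits without 1 array). The light signalling gene HYH had 0.40 and -1.55, and in photorespiration AT1G11860 rose by 0.57 in atbzip16, with 0.38 in the wild type, which passed with the block (adjusted p = 0.0202). The call in atbzip16 was lost after quantile normalization, with no filter, with no variance trend, from the 6 arrays compared, and without dark atbzip16 replicate 1 or 3, red-light Ler replicate 2 or red-light atbzip16 replicate 2 or 3 (0.40 to 0.69 over all fits without 1 array). The clock gene GI had 0.17 and 0.57, the latter passing with the block and not without it (adjusted p = 0.00119). The ethylene regulator EIN3 had -0.04 and -0.10, the cell cycle gene PRL -0.59 and 0.02, and the flavonoid genes UGT78D2 0.33 and 0.48 and UGT78D1 -0.13 and 0.86, none called with or without it. For the genotype differences in the dark and in red light, no member of these 12 lists passed by limma without the block, STZ having 0.94 and -0.96 and BIM1 0.33 and 0.06. Adjusted over the list alone, 1 light signalling gene was higher in the dark. The brassinosteroid and wound lists held 1 measured gene each, so that their p was unadjusted. At an unadjusted p under 0.05, 1 brassinosteroid and 1 wound gene were higher in the dark and 1 wound gene was lower in red light.

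The genes induced by abscisic acid had medians of -0.89 to -0.70 for the genotype difference in red light over the fits without 1 array, and the seed-maturation genes -0.08 to 0.24. A smaller share of seeds in red-light atbzip16 was weighed against the lower abscisic-acid-induced transcripts and left undecided, since it would lower the seed-maturation genes too and the range of their median includes 0. In the dark the abscisic-acid-induced list had -0.33, -0.46 and -0.20 in the 3 replicate pairs. A set of 23 probe sets at least 8-fold higher in red light had a median genotype difference of 0.11 in the dark and -0.15 in red light. Of 27 families of genes with a shared symbol, camera called 1 in 1 contrast: the 31 UGT genes, glycosyltransferases, in the dark (median 0.16, adjusted p = 0.0214, and adjusted p = 0.136 with an estimated correlation), with 0 members called by limma and 3 at an unadjusted p under 0.05.

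Replicate 1 stood apart from replicates 2 and 3 in all 4 groups. With group means removed, limma called 5278 probe sets between replicate 1 and the others, 2357 higher and 2921 lower, and 0 between replicates 2 and 3, where 489 had an unadjusted p under 0.05. Residual correlations between replicate 1 arrays of different groups were 0.317 to 0.505. In replicate 1, the chlorophyll list had a median of -0.51 with 6 of 9 members lower (camera adjusted p = 7.74e-05, and 0.0199 with an estimated correlation), the photosystem list one of -0.44 (adjusted p = 0.000187, and 0.0562 with an estimated correlation) and the plastid-encoded list one of -0.24 (adjusted p = 0.000139, and 0.396 with an estimated correlation). The labels name no batch, and each group holds 1 such array, so the replicate block carries this difference.

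The free-text descriptions of 6 samples contradict their titles. If the descriptions were right, photosystem transcripts would part Ler from atbzip16, but the lowest photosystem list median among arrays titled red light lay 0.969 above the highest among those titled etiolated.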
